A study of Homo sapiens with 6 samples.

How the data were processed

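RNA expression was measured by sequencing in cells labelled Huh7, a line derived from a human hepatocellular carcinoma. The 6 libraries fell into 2 groups of 3 by their labels, NC and NACER_ASO, the second of which the series describes as a knockdown of the long non-coding RNA NACER. Each library also carried a set number, 2, 5 or 6, and each set held 1 library of each group. Per the labels' protocols, total RNA was extracted with Trizol and each library was made from 1 ug of total RNA with the Illumina TruSeq Stranded mRNA LT kit, which selects polyadenylated RNA. The labels do not say whether the sets were separate cultures, so p-values measure the spread between these libraries, part of which may be technical.

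The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the fragments of the library) for RefSeq transcripts, with a gene symbol, gene identifier, length and hg19 locus for each, per the file headers. Per the submitters' processing notes, FastQC 0.11.5, Bowtie2 2.2.6 and StringTie 1.3.3b were used with the hg19 build. Their roles and settings, and whether strand was used in the estimates, are not given in the sources used here. The table held 63714 transcript rows under 27689 gene symbols, of which 11711 rows were at 0 in all 6 libraries. No read counts were used, so no count model was fitted. An FPKM estimate divides reads among overlapping isoforms and near-identical copies, so transcripts of 1 gene, small RNAs inside host genes, readthrough genes and genes with processed copies are less certain than the rest. FPKM is relative to each library's total, so an overall change in RNA per cell would not be seen.

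Depth was looked for in the low values. In transcripts of genes with 1 isoform, the most frequent low product of FPKM and length implied 15.6, 24.4 and 23.9 M fragments in NC sets 2, 5 and 6, and 21.9, 28.2 and 24.0 M in NACER_ASO sets 2, 5 and 6. Between 26.3% and 39.0% of the low values lay within 2% of a whole multiple of that step, so whole reads were not recovered and these depths are rough. Values near the filter rest on few fragments and were least precise in NC set 2, the shallowest library by this measure.

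Gene values were the sums of the FPKM of all transcripts of a symbol. Genes with at least 1 FPKM in at least 3 libraries were kept (13576 genes), log2(FPKM + 1) was taken, and limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend and the group as its only term. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Errors are given as SD over 3 libraries or as the SE or 95% confidence interval of the limma fit. The same fit was run on 23390 transcripts. Single genes of interest were also compared by an exact permutation test, for which 3 against 3 libraries cannot go below p = 0.1.

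For gene lists, camera was run with a preset inter-gene correlation of 0.01 and with the variance trend of the gene fit. It was repeated with the correlation estimated from the data, and fry was run beside it. Of 33 lists, 31 had at least 5 genes tested. The list of genes tied to the study's title had 4 and was described gene by gene, and of the mitochondrially encoded genes 0 were tested. The lists covered NRF2 and p53 targets, cyclin-dependent kinase inhibitors and polo-like kinases, S phase, G2 and mitosis, liver secreted proteins, liver transcription factors, xenobiotic and bile acid metabolism, cholesterol synthesis, lipogenesis, fatty acid oxidation, glycolysis, gluconeogenesis and the urea cycle, hypoxia, the ATF4 response, endoplasmic reticulum chaperones, heat shock, immediate early genes, interferon response, acute phase and NF-kB targets, the BCL2 family, TGF-beta and mesenchymal genes, ribosomal proteins, nuclear respiratory chain subunits, microRNA machinery, RNase H, paraspeckle and nuclear decay genes, histones, long non-coding RNAs of liver or general interest, and markers of stromal, immune and bile duct cells.

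The groups, tests, lists, most of the other settings tried and the rule for named genes were set before the data were examined. The rule named the genes of the study's title (NFE2L2, KEAP1, PLK2 and CDKN1A), the 10 genes in each direction with the largest change among those past the threshold and on the same side of NC in all 3 sets (filled up by smallest p where fewer passed), the 3 members with the smallest p in each list called by camera and in the NRF2 and p53 lists, and the 3 transcripts in each direction with the smallest p. The first run of camera had no variance trend, and the trend was switched on after its result had been seen, since the planned test used the gene-level fit. The level of NACER itself is not analysed here, so the knockdown was not checked through its target.

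The set numbers were tested as pairs. After subtraction of the group means, libraries of the same set correlated across genes at 0.90, 0.97 and 0.90 in sets 2, 5 and 6, whereas the highest correlation with a library of another set was 0.06. The first 2 principal components, with 71.1% and 22.8% of the variance, separated the sets. The set numbers therefore paired the libraries, and a fit with the set number as a block was run beside the fit without it.

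The fits were tested on simulated data that kept the set levels of each gene, with variances drawn from the fitted prior and 200 of 13576 genes changed in each of 5 runs. The fit without the block recovered 0% of genes changed 1.5-fold, 2-fold and 4-fold. The fit with the block recovered 47.8% of the 1.5-fold, 93.4% of the 2-fold and 100% of the 4-fold changes. These shares hold for 200 changed genes with errors drawn independently. The folds were set on the log2(FPKM + 1) scale, so for low genes they stand for larger changes in FPKM. An absence of calls with the block therefore does not exclude 2-fold changes of single genes in the real data. Other settings covered the pseudocount, the filter, 3 scalings, array weights, the block, the most abundant transcript in place of gene sums, and the leaving out of each library. Further combinations were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.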

Results

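Polyadenylated RNA of cells labelled Huh7, a hepatocellular carcinoma line, was profiled in 3 NC and 3 NACER_ASO libraries, with 1 library of each group in each of sets 2, 5 and 6. Between 12738 and 14635 genes per library had at least 1 FPKM. The 10 most abundant genes took between 6.07% and 9.61% of the summed FPKM, with the 2 highest shares in set 5. The libraries separated by set on the first 2 principal components and by group on the next, which held 3.19% of the variance.

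**Figure D1:**
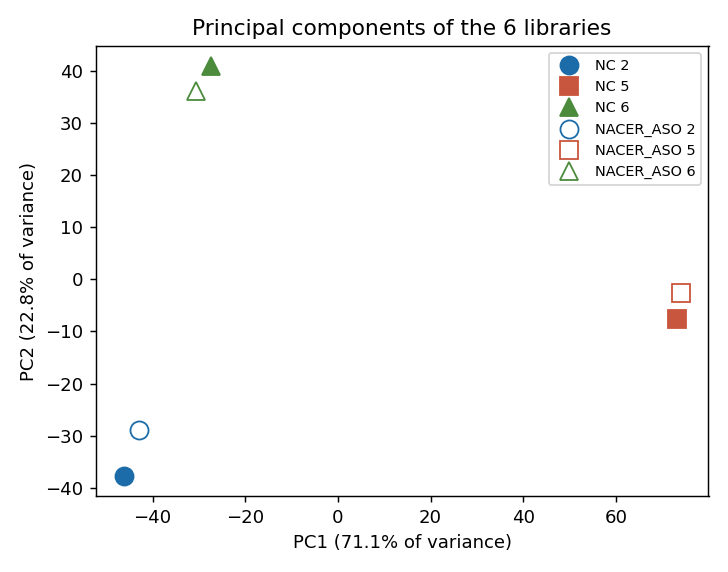
Principal components of log2(FPKM + 1) over 13576 genes, with PC1 (71.1% of the variance) on the x axis and PC2 (22.8%) on the y axis. Each point is 1 library, filled for NC and open for NACER_ASO, and the 2 libraries of each set lie next to each other.

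The series title ties NACER, described there as a liver-specific transcript, to the transcription factor Nrf2, the kinase Plk2 and the cell cycle inhibitor p21. None of these genes differed between the groups beyond the spread of the libraries. That spread includes the set differences, and the fit without the block recovered 0% of 4-fold changes on simulated data. NFE2L2, which encodes Nrf2, had 115.3 ± 30.0 FPKM (SD, n = 3) in NC and 106.1 ± 24.4 in NACER_ASO, and was lower in NACER_ASO in 3 of 3 sets. KEAP1, which encodes the adaptor that targets Nrf2 for degradation, had 38.7 ± 1.53 FPKM in NC and 37.9 ± 6.69 in NACER_ASO. PLK2 had 39.4 ± 36.9 FPKM in NC and 38.4 ± 31.7 in NACER_ASO. CDKN1A, which encodes p21, had 42.9 ± 7.14 FPKM in NC and 45.5 ± 17.4 in NACER_ASO.

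The log2 difference, NACER_ASO minus NC, was -0.11 for NFE2L2 (SE 0.26, 95% confidence interval -0.75 to 0.52) and -0.04 for KEAP1 (SE 0.19, interval -0.50 to 0.41). It was 0.07 for PLK2 (SE 1.11, interval -2.61 to 2.75) and 0.03 for CDKN1A (SE 0.30, interval -0.68 to 0.74). The adjusted p of each was 0.999994 in limma, and the two-sided exact permutation p was 0.7 for NFE2L2, 1 for KEAP1, 0.8 for PLK2 and 0.9 for CDKN1A. The wide interval of PLK2 came with levels that differed by set, from 6.06 FPKM in NC set 5 to 79.1 FPKM in NC set 2. The limma and permutation tests above ignore the pairing by set. With the set number as a block, the SE was 0.060 for NFE2L2, 0.089 for KEAP1, 0.090 for PLK2 and 0.11 for CDKN1A. The adjusted p of the blocked limma fit was 0.488, 0.863, 0.764 and 0.919 in that order. Leaving out 1 library turned the sign of some differences, but such a fit also leaves the sets unbalanced between the groups, so the set differences enter it. NFE2L2 was at 0.082 without NC set 2 and 0.061 without NACER_ASO set 6, and KEAP1 at 0.10 without NACER_ASO set 2. PLK2 was at -0.89 without NC set 5, -0.60 without NACER_ASO set 2 and -0.16 without NACER_ASO set 6. CDKN1A was at -0.059 without NC set 2, -0.0058 without NC set 5 and -0.26 without NACER_ASO set 6, and at -0.014 with median-of-ratios scaling. In hg19, NFE2L2 lies on chromosome 2 from 178095031 to 178129859 with 8 annotated transcripts, and KEAP1 on chromosome 19 from 10596796 to 10614054 with 2. PLK2 lies on chromosome 5 from 57749810 to 57755966 with 2, and CDKN1A on chromosome 6 from 36644237 to 36655116 with 5.

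**Figure D2:**
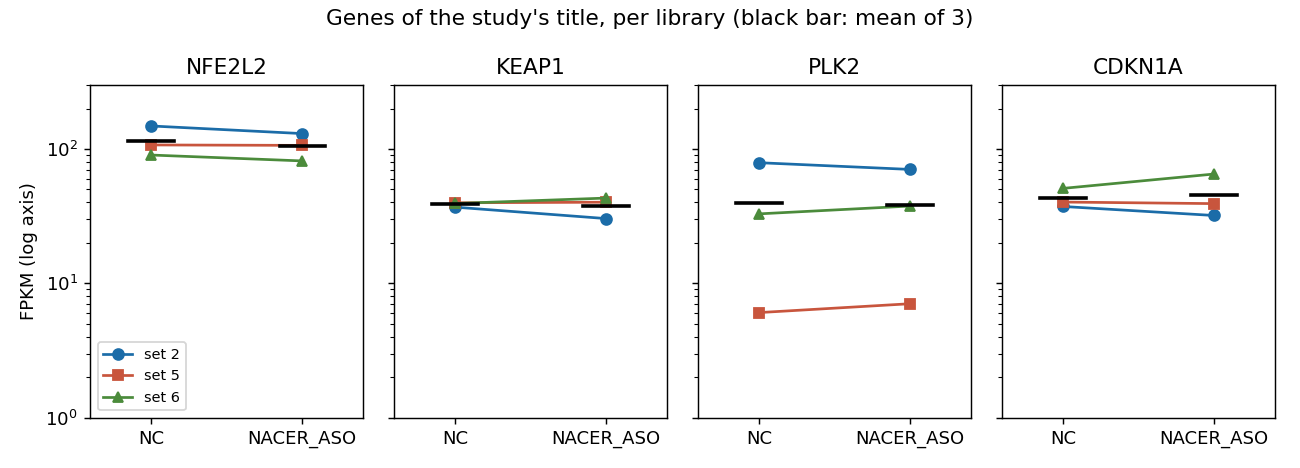
FPKM on a log axis for NFE2L2, KEAP1, PLK2 and CDKN1A in each library, with lines joining the NC and NACER_ASO libraries of a set and black bars at the mean of 3 libraries. PLK2 ranged from 6.06 to 79.1 FPKM between sets, while its 2 group means were 39.4 and 38.4 FPKM.

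Across all genes, none passed adjustment. The genes with the smallest p that kept their sign in every set included small RNAs and RPL13A, with lower values in NACER_ASO, and several mRNAs with higher values. RPL13A, a ribosomal protein gene (chromosome 19, 49990811 to 49995564), had 730.0 ± 60.5 FPKM in NC and 470.0 ± 47.1 in NACER_ASO, a log2 difference of -0.64 (SE 0.17). The H/ACA small nucleolar RNAs SNORA71D (-1.25, SE 0.30), SNORA66 (-1.16, SE 0.39) and SNORA71B (-0.89, SE 0.26) and the microRNA gene MIR664B (-1.43, SE 0.53) were lower in 3 of 3 sets. With the set number as a block, their SEs were 0.135, 0.126, 0.148 and 0.145 in that order. Their adjusted p in the blocked limma fit was 0.151, 0.151, 0.297 and 0.148. The other SEs in this paragraph and the next come from the fit without the block, so they include the set differences. Of 185 small RNAs hosted in introns, 51 were lower and 7 higher in all 3 sets, with medians of -0.32, -0.10 and -0.11 in sets 2, 5 and 6. Lower in 3 of 3 sets as well were INO80C, a subunit of a chromatin remodelling complex (-0.70, SE 0.24), MRPL10, a mitochondrial ribosomal protein gene (-0.89, SE 0.30), BBC3, which encodes the pro-apoptotic protein PUMA (-0.86, SE 0.34), SPRYD4 (-0.52, SE 0.20) and the readthrough gene ERV3-1-ZNF117 (-0.98, SE 0.26).

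Higher values in 3 of 3 sets were found for the readthrough gene HNRNPUL2-BSCL2, at 8.11 ± 2.03 FPKM in NC and 14.2 ± 3.04 in NACER_ASO (0.75, SE 0.26), and for FAM222A (0.77, SE 0.30), NATD1 (0.72, SE 0.29), METRNL (0.63, SE 0.26), GPR19 (0.62, SE 0.27), EBPL (0.60, SE 0.25), the interferon-inducible gene IFI6 (0.57, SE 0.24) and MZT2B (0.38, SE 0.16). The chemokine scavenger ACKR2 (0.72, SE 0.27) and the glutathione transferase gene GSTT2B (0.94, SE 0.37) also did so, from NC means of 0.421 and 0.369 FPKM that lay below the filter. With a pseudocount of 0.1 the differences of low genes were larger, at 1.48 for ACKR2, 2.76 for GSTT2B, 1.16 for NATD1, -2.17 for SNORA71D and -1.57 for ERV3-1-ZNF117. GSTT2B was at 1.4999 after rescaling to equal sums, and EBPL at 0.37 with array weights. Set 5 showed little of the difference in MRPL10 (-1.33, -0.03 and -1.30 in sets 2, 5 and 6) and BBC3 (-0.90, -0.09 and -1.58). With the block, MRPL10 was at -1.32 and EBPL at 0.27 without set 5, and BBC3 at -0.50 without set 6. MIR664B was at -0.92 without NC set 2, which held 11.3 FPKM against 2.74 and 3.84 in NC sets 5 and 6. Readthrough genes, small RNAs inside introns of host genes, GSTT2B, which has a near-identical neighbour, and RPL13A, which has processed copies, are uncertain, since reads can be divided between them and the overlapping or related sequence. In all, limma called 0 of 13576 genes, with a smallest adjusted p of 0.999994, and 20 genes had an unadjusted p under 0.05 (8 higher, 12 lower). The chance count of 678.8 does not hold for this fit, which leaves the set differences in its error. On simulated data it gave 0.0673% of unchanged genes an unadjusted p under 0.05. With the set number as a block, limma also called 0 genes, with a smallest adjusted p of 0.0762. In that fit 1685 had an unadjusted p under 0.05 (1201 higher, 484 lower) against 678.8 by chance. On simulated data the blocked fit gave 4.88% of unchanged genes such a p. In NACER_ASO, 3694 genes (27.2%) were higher in all 3 sets and 1499 (11.0%) were lower in all 3. The median difference over all genes was 0.041, but -0.00029 with median-of-ratios scaling, so the balance of higher and lower genes depends on the scaling.

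Of the 31 gene lists, 7 were called by camera, 6 of them lower and 1 higher in NACER_ASO. Values given without 1 library come from fits in which the sets were unbalanced between the groups. No member of any of them passed over all genes or adjusted over the list alone (0 genes in each), and with an estimated correlation 0 lists were called. With the set number as a block, 0 members passed over all genes. Adjusted over the list alone, the blocked fit called NEAT1 and MALAT1 lower. These same 2 genes were the calls in both the long non-coding RNA list and the RNase H, paraspeckle and decay list. It also called 1 ribosomal protein gene, 2 BCL2 family genes and 1 immediate early gene lower, and 1 NRF2 target and 1 glycolysis gene higher. Long non-coding RNAs of liver or general interest were lower in 7 of 12 genes in all 3 sets and higher in 1, with a median of -0.21 (camera adjusted p = 0.000186, and adjusted p = 0.973 with an estimated correlation). NEAT1, the scaffold RNA of paraspeckles (chromosome 11, 65190269 to 65213009), had 119.5 ± 68.8 FPKM in NC and 57.8 ± 29.0 in NACER_ASO, and its log2 difference was -1.12, -0.71 and -1.17 in sets 2, 5 and 6. MALAT1, a nuclear speckle RNA (chromosome 11, 65265209 to 65273983), had 39.9 ± 23.5 and 21.4 ± 10.9 FPKM, with -0.95, -0.61 and -0.90 in the 3 sets. GAS5 had 234.7 ± 64.2 and 199.5 ± 32.2 FPKM. Without NC set 2, NEAT1 was at -0.56, MALAT1 at -0.38 and GAS5 at -0.0044. This call ended without NC set 2 (adjusted p = 0.363) and without NACER_ASO set 6 (adjusted p = 0.0885), and with no filter on low values (adjusted p = 0.0545). With the block and the preset correlation it held when both libraries of a set were left out. The camera adjusted p was 0.00248 without set 2, 1.12e-06 without set 5 and 5.88e-08 without set 6. A list of RNase H, paraspeckle and nuclear decay genes was also called lower (camera adjusted p = 0.0440, and adjusted p = 0.973 with an estimated correlation), although its median was -0.01 and its mean -0.11, with 4 of 16 genes lower and 4 higher in all 3 sets. NEAT1 and MALAT1 are members of this list as well, and the next member, the splicing and paraspeckle factor SFPQ, had 140.3 ± 19.1 FPKM in NC and 124.2 ± 10.6 in NACER_ASO. That call ended without NC set 5 (adjusted p = 0.155), NC set 6 (adjusted p = 0.459), NACER_ASO set 2 (adjusted p = 0.287), NACER_ASO set 5 (adjusted p = 0.171) or NACER_ASO set 6 (adjusted p = 0.0698). It also ended with the block without both libraries of set 2 (adjusted p = 0.151) or set 6 (adjusted p = 0.141) and with array weights (adjusted p = 0.0647). Further settings that ended it were no filter (adjusted p = 0.0904) or the filter of 5 FPKM (adjusted p = 0.0833), quantile normalization (adjusted p = 0.285), the block with array weights (adjusted p = 0.129) and the list test without the variance trend (adjusted p = 0.0539).

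Replication-dependent histone genes, which are transcribed in S phase and mostly lack a poly(A) tail, were lower in 7 of 12 genes in all 3 sets and higher in 0 (camera adjusted p = 0.000211, and adjusted p = 0.973 with an estimated correlation). Their median log2 difference was -0.93 in set 2, -0.21 in set 5 and -0.05 in set 6. HIST1H1E had 6.28 ± 8.09 FPKM in NC and 1.68 ± 1.66 in NACER_ASO, HIST1H2BC had 12.0 ± 9.19 and 6.85 ± 2.52, and HIST1H4C had 5.47 ± 6.71 and 2.21 ± 2.44. The call ended without NC set 2 (adjusted p = 0.397) and NC set 5 (adjusted p = 0.737), and without NACER_ASO set 6 the direction turned (adjusted p = 0.804). With the block and the preset correlation it held when both libraries of a set were left out. The camera adjusted p was 0.0374 without set 2, 8.64e-09 without set 5 and 3.38e-13 without set 6. Without NC set 2, HIST1H1E was at -0.11 (-1.01 with all libraries), HIST1H2BC at 0.0066 and HIST1H4C at 0.12. S phase genes, tested as a separate list, were not called (median 0.07, camera adjusted p = 0.533).

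Ribosomal protein genes were called lower (camera adjusted p = 0.000270, and adjusted p = 0.973 with an estimated correlation) with 3 of 74 lower and 0 higher in all 3 sets. The median over members was -0.22 in set 2, 0.07 in set 5 and 0.04 in set 6, so the sign differed between sets. Besides RPL13A, RPL28 had 150.2 ± 12.2 FPKM in NC and 135.7 ± 16.4 in NACER_ASO, while RPS16 had 694.7 ± 149.2 and 855.9 ± 320.9. The direction turned without NC set 5 (adjusted p = 0.0879) and without NACER_ASO set 2 (higher, adjusted p = 0.0114), and with the block it turned without both libraries of set 2 (higher, adjusted p = 0.0159). The call ended without NACER_ASO set 6 (adjusted p = 0.451) and with quantile normalization (adjusted p = 0.861). RPS16 was at -0.015 without NACER_ASO set 5. Immediate early genes, which respond within minutes to growth and stress signals, were called lower (camera adjusted p = 0.0162, and adjusted p = 0.973 with an estimated correlation), with 6 of 21 lower and 2 higher in all 3 sets and medians of -0.53, -0.14 and 0.09 in sets 2, 5 and 6. KLF6 had 21.2 ± 15.5 FPKM in NC and 11.3 ± 7.23 in NACER_ASO, MYC had 59.3 ± 33.2 and 44.8 ± 15.9, and JUND had 56.8 ± 30.9 and 41.5 ± 14.97. Without NC set 2 the list was called in the other direction (adjusted p = 0.0349), with MYC at 0.098, JUND at 0.034 and KLF6 at -0.19 (-0.73 with all libraries). Without NACER_ASO set 5 the direction turned (adjusted p = 0.209), and without NC set 6 the call ended (adjusted p = 0.178). With the set number as a block and both libraries of set 2 left out, the call ended as well (adjusted p = 0.424). It ended also with median-of-ratios scaling (adjusted p = 0.0581), quantile normalization (adjusted p = 0.151), array weights (adjusted p = 0.0663) and no filter (adjusted p = 0.0647).

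Interferon-stimulated genes and innate sensors were called higher (camera adjusted p = 0.00200, and adjusted p = 0.973 with an estimated correlation), with 12 of 20 higher and 1 lower in all 3 sets and medians of 0.29, 0.11 and 0.14 in sets 2, 5 and 6. IFI6 had 10.5 ± 0.389 FPKM in NC and 16.5 ± 4.47 in NACER_ASO, IFIH1, a sensor of double-stranded RNA, had 3.20 ± 0.736 and 4.65 ± 0.920, and MX1 had 4.18 ± 1.80 and 7.55 ± 4.75. MX1, at 0.62 with all libraries, was at 0.21 without NACER_ASO set 2, 0.28 without NC set 5 and 1.11 without NACER_ASO set 5. With the block without set 2, IFIH1 went from 0.43 to 0.18 and MX1 to 0.38. The call ended without NC set 5 (adjusted p = 0.455) and without NACER_ASO set 2 (adjusted p = 0.417). With the block and the preset correlation it held when both libraries of a set were left out. The camera adjusted p was 0.0413 without set 2, 0.00224 without set 5 and 0.000873 without set 6. The BCL2 family was called lower (camera adjusted p = 0.00988, and adjusted p = 0.973 with an estimated correlation), with 6 of 14 lower and 2 higher in all 3 sets. Its members with the smallest p were BBC3 (4.67 ± 1.79 and 2.12 ± 0.955 FPKM), BIK (4.75 ± 1.17 and 6.82 ± 1.72) and BAX (79.4 ± 4.59 and 68.5 ± 9.17), all of which promote apoptosis. That call ended without NC set 2 (adjusted p = 0.196), NC set 6 (adjusted p = 0.698), NACER_ASO set 2 (adjusted p = 0.126) and NACER_ASO set 5 (adjusted p = 0.515). It also ended with the block without both libraries of set 2 (adjusted p = 0.0907), with no filter (adjusted p = 0.0647) and with the filter of 5 FPKM (adjusted p = 0.0909).

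**Figure D3:**
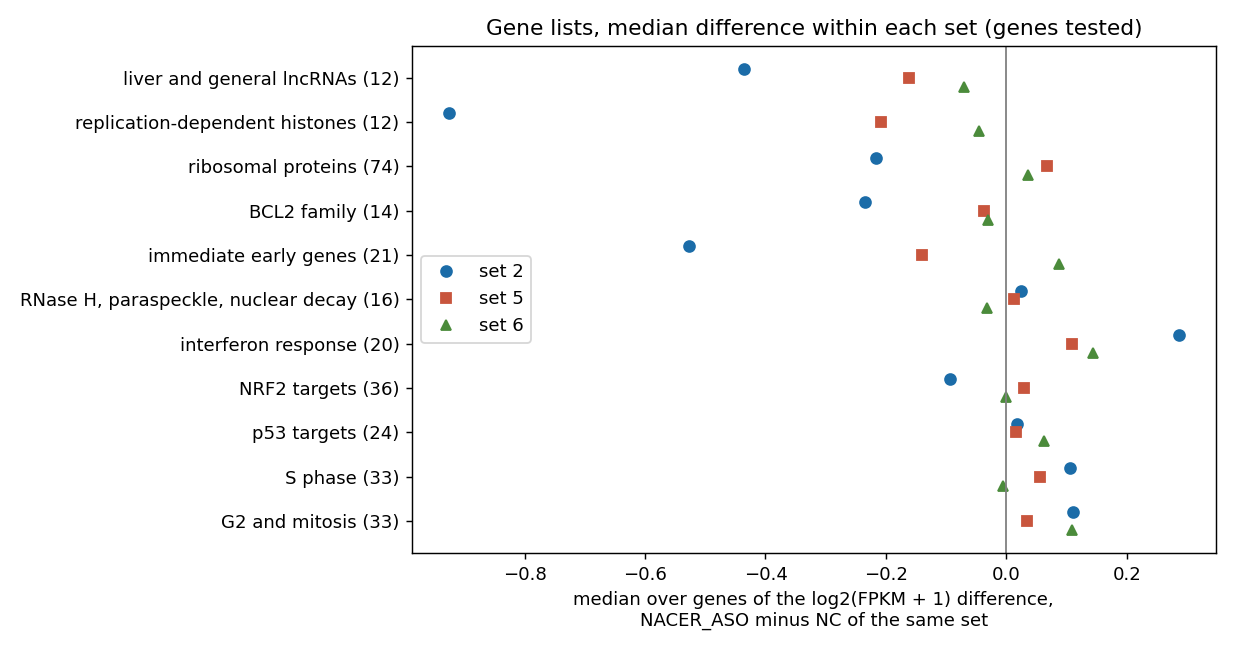
Median over the genes of a list of the log2(FPKM + 1) difference, NACER_ASO minus NC of the same set, on the x axis, for the 7 called lists and 4 further lists on the y axis, with the number of genes tested in brackets and a symbol for each set. Set 2 lay lowest for histones (-0.93), immediate early genes (-0.53) and ribosomal proteins (-0.22). The interferon, p53 target, and G2 and mitosis lists lay above 0 in all 3 sets.

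NRF2 targets, the antioxidant and detoxification genes that Nrf2 drives, were lower in 10 of 36 genes and higher in 6 in all 3 sets, with a median of -0.03. The list was not called (camera adjusted p = 0.104, and adjusted p = 0.973 with an estimated correlation). With the set number as a block it was called lower (adjusted p = 0.0278, and adjusted p = 0.857 with an estimated correlation), but not when both libraries of set 2 (adjusted p = 0.506) or set 6 (adjusted p = 0.114) were left out. PIR had 35.7 ± 9.78 FPKM in NC and 45.4 ± 12.1 in NACER_ASO, EPHX1 had 30.2 ± 16.4 and 38.5 ± 13.0, and the cystine transporter gene SLC7A11 had 12.3 ± 2.69 and 9.71 ± 2.15, so the 3 members with the smallest p went in both directions. The list was also called lower without NC set 2 (adjusted p = 6.33e-05) and without NACER_ASO set 5 (adjusted p = 6.29e-05), and its direction turned without NC set 5 (adjusted p = 0.455) and NACER_ASO set 2 (adjusted p = 0.127). Targets of p53 were lower in 4 of 24 genes and higher in 6 in all 3 sets and were not called (camera adjusted p = 0.406). Camera ranked this list lower although its median was 0.04, and it ranked it higher without NACER_ASO set 5 (adjusted p = 0.803). RRM2B, a ribonucleotide reductase subunit gene, had 3.92 ± 0.530 FPKM in NC and 6.97 ± 3.32 in NACER_ASO, beside the lower values of BBC3 and BAX.

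With the set number as a block, acute phase and NF-kB genes were called lower (adjusted p = 0.00647, and adjusted p = 0.857 with an estimated correlation) and fatty acid oxidation genes higher (adjusted p = 0.0278, and adjusted p = 0.857 with an estimated correlation), neither of which was called without it (adjusted p = 0.161 and 0.146). Of the acute phase list 7 of 21 genes were lower and 1 higher in all 3 sets, with medians of -0.26, -0.03 and 0.06 in sets 2, 5 and 6, so the sign turned in set 6. Of the fatty acid oxidation list 10 of 18 were higher and 1 lower, with medians of 0.20, 0.08 and 0.07. The remaining lists were not called in either fit. Their medians were 0.07 for G2 and mitosis, 0.14 for xenobiotic and bile acid metabolism, 0.13 for gluconeogenesis and the urea cycle, -0.02 for TGF-beta and mesenchymal genes, 0.03 for the ATF4 response and 0.03 for heat shock. They were 0.05 for cyclin-dependent kinase inhibitors and polo-like kinases, 0.04 for endoplasmic reticulum chaperones, 0.06 for hypoxia, -0.0017 for cholesterol synthesis, 0.05 for liver secreted proteins, -0.01 for microRNA machinery, 0.02 for glycolysis, 0.06 for liver transcription factors, 0.02 for lipogenesis and 0.03 for the respiratory chain. Markers of other cell types were not called either, with medians of 0.06 for bile duct, 0.07 for immune and 0.06 for stromal markers. Camera compares the test statistics of a list with those of all other genes, whose median difference was 0.041. The direction it gives need not follow the median or mean difference of a list. It ranked the ATF4, heat shock, hypoxia, liver secreted protein, liver transcription factor, bile duct and stromal lists lower although their medians and means were above 0. It ranked cholesterol synthesis and microRNA machinery lower with medians below 0 and means of 0.042 and 0.035. Fry, which tests whether a list's genes move on balance to 1 side, called 0 lists with and without the block.

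At the level of transcripts, the differences with the smallest p were in isoforms of genes whose summed FPKM differed little between groups. An isoform of EGFR, the epidermal growth factor receptor, was listed at 0 in 3 of 3 NC libraries and at 11.3, 11.9 and 8.46 FPKM in NACER_ASO sets 2, 5 and 6, but the gene sum differed by -0.09 on the log2 scale. Isoforms of CKAP2 (2.28, SE 0.35) and R3HDM1 (1.85, SE 0.31) were higher, and isoforms of ATF2 (-1.84, SE 0.27), DAG1 (-1.72, SE 0.25) and RIPOR1 (-1.49, SE 0.23) were lower, where the gene sums differed by 0.17, 0.23, 0.04, -0.07 and 0.06. Limma called 0 of 23390 transcripts, with a smallest adjusted p of 0.109, and 220 had an unadjusted p under 0.05. As for genes, the chance count of 1169.5 does not hold for this fit, which leaves the set differences in its error. With the set number as a block, limma called 0 transcripts, with 1415 at an unadjusted p under 0.05 against 1169.5 by chance. EGFR had 9 annotated transcripts, which overlap, so its isoform values are uncertain.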

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

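Some alternatives were added after the data had been seen: every combination of the set block or array weights with another pseudocount, filter or scaling (the block with median-of-ratios scaling was planned), the block with array weights, the block without both libraries of a set, the block with an estimated correlation, and camera without the variance trend. Without the block, all 20 alternatives called 0 genes, with 10 to 149 or, with array weights, 47 to 502 at an unadjusted p under 0.05. With the block alone, 0 genes were called (1685 at an unadjusted p under 0.05, against 20), also with pseudocount 0.1, no filter, the filter of 5 FPKM, quantile normalization or median-of-ratios scaling (1071 to 2269 at an unadjusted p under 0.05). After rescaling to equal sums 5 were called. With the block and array weights, 7 genes were called, and 4 with pseudocount 0.1, 0 with no filter (2909 at an unadjusted p under 0.05), 5 with the filter of 5 FPKM, 19 with rescaling to equal sums, 15 with median-of-ratios scaling and 161 with quantile normalization. The block without both libraries of set 2, 5 or 6 called 3, 14 and 58 genes (1, 2 and 5 higher, and 2, 12 and 53 lower). Among the genes named by the rule, MRPL10, MIR664B, KLF6, NEAT1 and MALAT1 passed without set 5 (adjusted p from 0.0164 to 0.0489). HNRNPUL2-BSCL2, GSTT2B, SNORA71D, ERV3-1-ZNF117, SNORA66, INO80C, MIR664B, NEAT1, MALAT1 and HIST1H4C passed without set 6 (adjusted p from 0.00475 to 0.0421). RMRP, singled out after its calls were seen, was called in 10 settings, and EID3 and RNU11, likewise, in 9. The cause of these differences was not tested. Transcripts called stayed at 0 in 10 alternatives. The lists called went from 7 to 3 with no filter, 0 with an estimated correlation (0 also with the block), 5 with the filter of 5 FPKM, quantile normalization or array weights, 6 with median-of-ratios scaling or without the variance trend, 10 with the block, 7 with the block and array weights, and 5, 11 and 8 with the block without set 2, 5 or 6, and ranged from 7 to 11 when 1 library was left out. The block changed no call other than those of the NRF2, acute phase and fatty acid oxidation lists. Leaving out 1 library gave log2 differences from -0.27 to 0.082 for NFE2L2, -0.14 to 0.10 for KEAP1, -0.89 to 0.97 for PLK2, -0.26 to 0.25 for CDKN1A, -0.59 to 0.098 for MYC, -0.81 to 0.034 for JUND, -1.05 to 0.0066 for HIST1H2BC, -1.39 to 0.12 for HIST1H4C and -0.015 to 0.56 for RPS16. The ranges were -1.43 to -0.19 for KLF6, -1.66 to -0.11 for HIST1H1E, -1.77 to -0.92 for MIR664B, -1.38 to -0.56 for NEAT1, -1.19 to -0.38 for MALAT1, -0.38 to -0.0044 for GAS5, -0.27 to -0.075 for SFPQ, -0.21 to -0.048 for RPL28 and -0.31 to -0.12 for BAX. They were 0.27 to 0.57 for BIK, 0.21 to 1.11 for MX1, 0.13 to 0.55 for PIR, 0.086 to 0.82 for EPHX1, -0.47 to -0.16 for SLC7A11 and 0.31 to 0.96 for RRM2B. It gave adjusted p from 7.51e-08 to 0.209 for immediate early genes, 1.86e-22 to 0.451 for ribosomal proteins, 2.40e-15 to 0.804 for histones, 6.29e-05 to 0.625 for NRF2 targets and 0.0698 to 0.940 for p53 targets. These fits leave sets unbalanced between groups, which by construction mixes set differences into them. Reversed values elsewhere were CDKN1A at -0.014 with median-of-ratios scaling, with or without the block, and at -0.13 with the block without set 6, KEAP1 at 0.026 with array weights and 0.072 with the block without set 2, where RPL28 was at 0.0096, and ribosomal proteins with adjusted p = 0.0159 with the block without set 2 and 0.850 with the block and array weights. Depth limits genes near 1 FPKM most in NC set 2, at an implied 15.6 M fragments.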

Other observations

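The comparisons of sets and the genes named in them were chosen after the data had been seen. So were the tests on S phase, on the counts of genes in other splits and on isoforms in other splits, the demand that the summed level of RPL13A and its copy vary little between sets, and the use of MALAT1 and NEAT1 beside detained-intron mRNAs. All 6 libraries were labelled Huh7, yet 11024 of 13576 genes differed between sets in limma (adjusted p under 0.05, group as a term, 2 libraries per set). Single genes differed widely. Set 5 had the E-cadherin gene CDH1 at 97.8 FPKM against 10.8 and 14.6 in sets 2 and 6, EPCAM at 206.9 against 18.99 and 32.1, APOA1 at 498.0 against 25.7 and 6.16, and AFP, the fetal liver protein gene, at 2810 against 839.5 and 225.9. Sets 2 and 6 had the mesenchymal filament gene VIM at 863.7 and 1029 FPKM against 52.3 in set 5, the keratin gene KRT19 at 68.3 and 96.1 against 1.87, and the proteoglycan gene LUM at 211.8 and 186.1 against 0.00837. The log2 difference of set 5 minus set 2 was 3.06 for CDH1 (SE 0.089), 4.23 for APOA1 (SE 0.073), -4.02 for VIM (SE 0.089) and -7.72 for LUM (SE 0.084). PLK2 followed the sets too, at 74.8, 6.55 and 35.3 FPKM in sets 2, 5 and 6. No label says what the set numbers stand for, and no explanation was tested. Whether the sets held the same cells was not tested either, so the identity of the cells rests on the labels.

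By list, set 5 was lower than set 2 in immediate early genes, with 21 of 21 members lower (median -2.65, camera adjusted p = 1.56e-06, and adjusted p = 0.535 with an estimated correlation), and in stromal markers, with 6 of 6 lower (median -1.91, adjusted p = 0.00618, and adjusted p = 0.535 with an estimated correlation). Ribosomal proteins were higher in set 5 than in set 2 in 50 of 74 members (median 0.43, adjusted p = 4.40e-12, and adjusted p = 0.599 with an estimated correlation). Not all liver genes were higher in set 5: liver secreted proteins were higher than in set 2 in 13 of 26 members and lower in 11 (adjusted p = 0.0562), and xenobiotic and bile acid genes were higher in 4 of 18 and lower in 12 (adjusted p = 0.427). Liver secreted proteins were lower in set 6 than in set 2 in 25 of 26 members (median -0.93, adjusted p = 3.47e-11, and adjusted p = 0.580 with an estimated correlation), among them ALB at 596.0 FPKM against 1124. With the sets as blocks, the 95% confidence intervals of the NACER_ASO minus NC difference narrowed to -0.26 to 0.03 for NFE2L2, -0.26 to 0.18 for KEAP1, -0.15 to 0.29 for PLK2 and -0.24 to 0.30 for CDKN1A, all of which still covered 0. CEBPB, singled out after its values were seen, was at 2.79, 4.97 and 44.5 FPKM in NC sets 2, 5 and 6 and at 55.6, 28.8 and 4.98 in NACER_ASO.

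Among 15 small RNAs with their own promoters, which mostly lack a poly(A) tail, 11 were lower in NACER_ASO in all 3 sets and 0 higher, with medians of -1.40, -1.25 and -0.34 in sets 2, 5 and 6, and among 56 replication-dependent histone genes 29 were lower and 0 higher, with -1.02, -0.40 and -0.03, but 185 small RNAs hosted in introns, which lack the tail too, had only -0.32, -0.10 and -0.11 (51 lower, 7 higher). RMRP and RNU11, named after their values were seen, had 206.0 ± 317.8 and 76.5 ± 104.6 FPKM in NC and 51.9 ± 76.8 and 16.3 ± 21.8 in NACER_ASO (SD, n = 3), and set 2 held the highest values of both. The tables argue against a loss of mRNAs under 700 bases, which lay at 0.0425 on average. Histone and ribosomal protein genes were left out of this class, so the value does not cover them. Ribosomal protein genes lay at -0.22, 0.07 and 0.04 in sets 2, 5 and 6. The short mRNAs of the class lay at -0.11, 0.09 and 0.16 in these sets, so lower in set 2 but far less than the small RNAs. These mRNAs cannot show whether much shorter RNAs, such as SNORA71D with 138 bases, were lost, so that account stays open for them. The tables also argue against fewer cells in S phase, with the S phase list at 0.0524. Less carry-over of RNA without a poly(A) tail through the selection may account for the lower values, since the median of histone genes minus that of polyadenylated histone variants was -0.459, but the histone median near 0 in set 6 and the small shift of the intron-hosted RNAs keep this account open. Less nuclear RNA in the lysates also stays open. The nuclear RNAs MALAT1 and NEAT1 lay at -1.04, -0.66 and -1.03 in sets 2, 5 and 6. How far these 2 RNAs depend on the poly(A) selection was not tested, so they cannot separate this account from less carry-over. The mRNAs with detained introns lay at -0.0155, in sums that mature mRNA can dominate. An effect of the NACER_ASO treatment stays open too and was not tested.

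RPL13A was lower in 3 of 3 sets (-0.54, -0.56 and -0.81), while its processed copy RPL13AP5 differed by -0.06, 2.01 and 2.53. Reads divided differently between the copies could give this, and the sum of both differed by 0.142 on average. The sum differed by -0.36, 0.38 and 0.40 in sets 2, 5 and 6 (SD 0.43), so the mean near 0 hides opposite signs, and in set 2 RPL13AP5 was not higher beside the lower RPL13A. The account therefore remains open, as does an effect of the treatment, which was not tested.

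Isoforms under 0.1 FPKM in all libraries of one group and at 1 FPKM or more in all of the other numbered 9 between NC and NACER_ASO, among them those of EGFR, ATF2, R3HDM1 and RIPOR1. The other 3 splits that part every set gave 5, 7 and 7. Unstable assignment of reads among isoforms may therefore account for most of them, since up to 7 such isoforms arose in groupings that follow no label. An effect of the treatment on single isoforms stays open: limma called 0 of 23390 transcripts, with a smallest adjusted p of 0.109 (220 at an unadjusted p under 0.05), and with the block 0, with 0.518 (1415).

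The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For genes past the threshold, the real split gave 0 and the highest other 0, so all 10 splits had as many. That comparison decides nothing, since the same fit recovered 0% of 4-fold changes on simulated data. For gene lists the real split gave 7 and the highest other 12, and 9 of 10 splits had as many. For transcripts the real split gave 0 and the highest other 8. With 0 in the real split all 10 had as many by definition, so this comparison decides nothing either. The splits that keep a set together had 397 to 2966 genes at an unadjusted p under 0.05, against 20 in the real split, which points to the sets as a structure of these libraries. Only 3 other splits part all 3 pairs as the real one does. With the set as a block they had 334, 225 and 545 genes at an unadjusted p under 0.05 against 1685 in the real split, each called 0 genes, and they called 7, 9 and 5 lists against 10.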
